A study of Caenorhabditis elegans with 16 samples.

How the data were processed

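Gene expression was measured by RNA sequencing of whole Caenorhabditis elegans. Per the labels' protocols, animals hatched synchronously were raised on Escherichia coli OP50, the usual laboratory food, or on Methylobacterium (Red in the labels), and were collected 48 h later at the L4 larval stage. Total RNA was extracted with a column kit. The 16 libraries form 4 groups of 4: wild type (WT) and odr-1lf mutants on each bacterium. The labels number the libraries of a group but do not say whether they came from separate cultures, so the p-values measure the spread between these libraries, which may be partly technical.

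The deposited table holds raw counts per gene, in whole numbers, with 1 column per library. The submitters' processing notes name CASAVA 1.8, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq2 1.18.0 and the ce11 genome build, without saying what each did. The annotation, the strand setting and any filter are not given in the sources used here, so reads of a gene and of an overlapping or antisense neighbour may not have been told apart. Columns were matched to libraries by the letters and numbers of their names. The letter O in first place stands for odr-1lf, and the letter N was read as WT because no other genotype remained. The second letter gives the bacterium. Of 46589 gene identifiers in the table, 46180 matched a single gene of the WBcel235 annotation, 3 matched several and 406 matched none; matched identifiers held 99.78% of the counts. Gene names and coordinates come from that annotation. No genome sequence was used, so sharing of reads between near-identical genes was not examined.

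Total counts ran from 18341457 to 27666414 per library. Ribosomal RNA took 0.25 to 3.912% of a library, mitochondrially encoded genes 0.904 to 1.792%, and the 10 most abundant genes 5.301 to 8.508%. No pair of replicates matched within sampling noise, with a chi-square per gene of 10.3 or more. In odr-1lf on OP50, replicates 1 and 3 (10.3) and replicates 2 and 4 (10.7) resembled each other most. The other pairs of that group gave 62.5 to 89.8, and pairs of the other groups 65.2 or more. These odr-1lf OP50 libraries may therefore not be fully independent, and tests that use them may understate the spread.

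Differential expression was tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr by group) in R 4.3.3. All 16 libraries entered a single fit with a coefficient per group, which tested 15640 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. Standard errors are the log2 fold change divided by the square root of the F statistic, with its sign removed. Levels are CPM, counts scaled to a common library size with the TMM factors, given as mean ± SD. The comparisons were the diet effect in each genotype, the genotype effect on each bacterium, and the interaction, which is the diet effect in odr-1lf minus that in WT. Where a group held no count of a gene, the fold is a lower bound computed from 3 counts over the group; with 1 to 3 counts the ratio is given with its exact 95% interval, which covers counting error only.

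A total of 32 gene lists, drawn up from gene names, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and again with the correlation estimated per list. Camera's adjusted p covers the 32 lists of a comparison. The list of mitochondrially encoded genes was taken by chromosome, because the annotation names those genes differently from the list as first written. A stage score per library was the first principal component of 407 genes from the lists of collagens, moulting, sperm, oocyte, germline and vitellogenin genes, and groups were compared by exact permutation.

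The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names odr-1, then per comparison the 6 highest and 6 lowest called fold changes among genes with a mean of 5 CPM in a compared group and non-overlapping values between groups, with at most 2 genes per name family, and up to 2 called members per list with the smallest adjusted p. Genes named outside the rule are said to be.

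The alternatives were DESeq2 1.42.0, relative log expression and upper-quartile factors, no low-count filter, a fit of only the 8 libraries compared, the replicate number as a block, a test against a log2 fold change of 1 (glmTreat), removal of the stage-linked lists, and leaving out each library in turn. A stage score covariate and removal of ribosomal RNA genes were added after the data had been seen, as was the replicate number as a block in the WT libraries alone, in the fit of all 16 or of the 8. The labels do not say what a replicate number marks. Deviations from the group means correlated over 0.1 in 4 of 4 same-numbered pairs of the WT diet comparison (0.278 to 0.711), so the numbers were taken to pair these libraries; this held in 0 of 4 pairs of the odr-1lf diet comparison and in 2 of 4 of each genotype comparison. This pairing was read from the same counts, so the number of calls with this block is no separate support for it or for the calls. In the fit of all 16 libraries the spread left after this block is shared with the odr-1lf libraries, which it was not taken to pair. The tests were tried on simulated counts with known changes. With 4 libraries per group, edgeR recovered 32% of 2-fold changes and 81% of 4-fold changes in the simulated WT diet comparison, 31% and 83.8% in the odr-1lf diet comparison, 24% and 87.9% in the genotype comparison on OP50, 25% and 86% in that on Methylobacterium, and 8% and 45.9% in the interaction, none with the wrong sign. The changed genes were drawn from those over 1 CPM in WT on OP50. Among unchanged genes edgeR made 10, 6, 7, 2 and 2 false calls in these comparisons, in the same order. DESeq2 made 44, 27, 45, 33 and 19, so its larger counts may hold more false calls. The simulated counts were drawn independently around the WT OP50 profile, with the spread that edgeR had estimated. They held no structure that genes share, such as stage, so the real libraries may give more false calls with either tool. No scaling moved the median log2 fold change of all genes by over 0.1.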

Results

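The series asks how gene expression differs between WT and odr-1lf animals raised on OP50 or on Methylobacterium. odr-1 encodes a receptor-type guanylyl cyclase that acts in olfactory neurons. RNA of whole L4 animals was sequenced in 4 libraries per group, with 18341457 to 27666414 counts each.

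odr-1 itself (R01E6.1, X, 13544729 to 13550990, minus strand, protein coding) was near the detection limit. WT libraries held 3, 5, 11 and 1 counts on OP50 and 4, 10, 31 and 7 on Methylobacterium, and odr-1lf libraries held 3, 1, 2 and 1 on OP50 and 5, 1, 2 and 8 on Methylobacterium. The mean was 0.226 ± 0.176 CPM in WT and 0.0803 ± 0.0396 CPM in odr-1lf on OP50, and 0.518 ± 0.480 CPM and 0.183 ± 0.135 CPM on Methylobacterium (SD, n = 4). The gene fell below the low-count filter. Fitted without that filter, its log2 fold change between genotypes was -1.45 ± 0.82 (SE) on OP50 and -1.5 ± 0.70 on Methylobacterium, with edgeR adjusted p of 0.66 and 0.88; without WT OP50 replicate 3 and WT Methylobacterium replicate 3 these were -0.82 and -0.61. These counts do not check the genotype labels, because the nature of the lesion is not stated and a mutant transcript can still be counted.

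In WT animals, 6 of 7 propionate shunt genes, 14 of 23 genes of the methionine and folate cycle and the desaturases fat-5 and fat-7 were lower on Methylobacterium, and the lipases fil-1 and fil-2, the saposin-like gene spp-9 and the infection-induced genes C32H11.4 and sysm-1 were higher. acdh-1, the acyl-CoA dehydrogenase of the propionate shunt that is widely used as a reporter of low vitamin B12, fell from 4256 ± 943 CPM on OP50 to 3.42 ± 0.563 CPM on Methylobacterium (SD, n = 4). fat-7, a fatty acyl-CoA desaturase, fell from 198 ± 16 to 2.31 ± 0.685 CPM. fil-1, a fasting-induced lipase, rose from 1.26 ± 0.390 to 21.1 ± 4.56 CPM.

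edgeR called 907 of 15640 genes in WT, 301 higher and 606 lower on Methylobacterium, of which 659 changed at least 2-fold. DESeq2 called 1384, 538 of them higher. Of the 7 propionate shunt genes, 6 fell and none rose; adjusted over the list alone, 7 fell. hphd-1, which oxidises 3-hydroxypropionate in this shunt, fell from 1672 ± 266 to 50.4 ± 11.2 CPM (adjusted p = 2.0e-09). In the methionine, S-adenosylmethionine and folate list, 14 of 23 members fell and 1 rose, and 15 fell and 2 rose adjusted over the list alone. pmp-5, an ABC transporter, changed by -4.58 ± 0.15 (log2, SE) and ahcy-1, the S-adenosylhomocysteine hydrolase, by -2.64 ± 0.17. These 2 lists were the ones called with an estimated correlation (adjusted p = 0.0032 and 0.0016), against 13 of 32 with the preset correlation. In the canonical B12-dependent propionate pathway 2 of 8 fell, and 2 fell and 1 rose adjusted over the list alone. These were mmaa-1 (-2.35 ± 0.21), which assists methylmalonyl-CoA mutase, and cblc-1 (-1.70 ± 0.24), which processes vitamin B12.

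**Figure D1:**
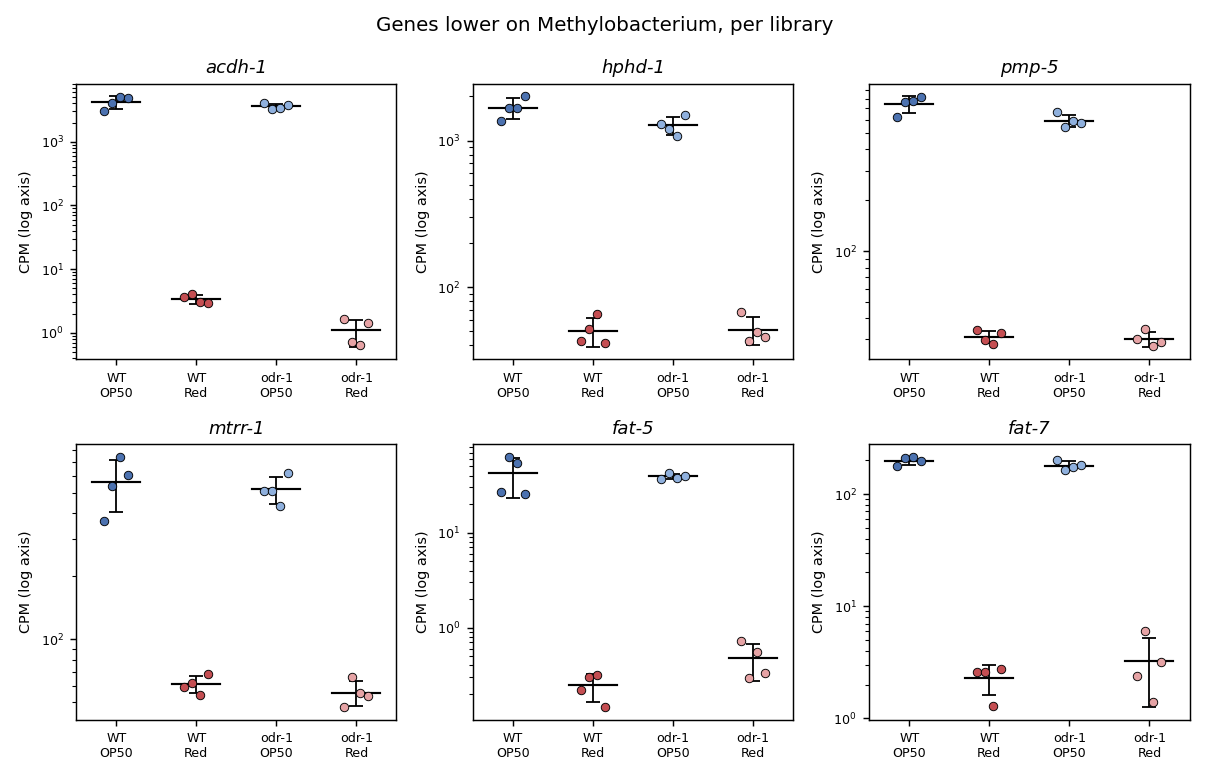
CPM on a log axis in each library of the 4 groups for 6 genes; points are libraries, long bars are means and whiskers are SD (n = 4). acdh-1 lay at a mean of 4256 CPM in WT and 3610 CPM in odr-1lf on OP50, and at 3.42 and 1.1 CPM on Methylobacterium.

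Among lipid genes in WT, 6 of 27 members of fatty acid synthesis, desaturation and elongation fell and none rose, with 7 fallen adjusted over the list alone (camera adjusted p = 0.30 with an estimated correlation). fat-5, a desaturase, changed by -7.37 ± 0.41 and fat-7 by -6.42 ± 0.39; fat-5, fat-6 and fat-7 are similar in sequence, so their counts are uncertain where reads could be split. In beta-oxidation 5 of 36 fell and 1 rose, and 5 fell and 2 rose adjusted over the list alone (adjusted p = 0.61 with an estimated correlation). The fallen members included the thiolase kat-1 (-1.23 ± 0.17). cpt-3, a carnitine palmitoyltransferase, held 75 counts on OP50 and 2 on Methylobacterium, a ratio of 43.9 (95% interval 11.7 to 370). In lipolysis and lipid binding 4 of 34 rose and 5 fell, and 4 rose and 6 fell adjusted over the list alone. In the fasting response 4 of 16 rose and 2 fell, and 4 rose and 6 fell adjusted over the list alone. The lipases fil-1 and fil-2, which are in both lists, changed by 4.05 ± 0.29 and 6.13 ± 0.52; the latter was 7.15 without WT OP50 replicate 4.

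Genes of defence and detoxification moved both ways in WT. Of 143 C-type lectins and lysozymes 11 rose and 19 fell, and 20 rose and 25 fell adjusted over the list alone. The lectin clec-48 fell from 268 ± 74.1 to 18.5 ± 5.88 CPM and the lysozyme lys-5 from 12.26 ± 6.76 to 0.301 ± 0.108 CPM. Of 57 antimicrobial peptide genes 4 rose and none fell by edgeR or adjusted over the list alone, led by the saposin-like spp-9, from 0.0876 ± 0.0576 to 78.7 ± 74.9 CPM (adjusted p = 0.00021). In the pathogen response list 5 of 27 rose and 4 fell, and 5 rose and 6 fell adjusted over the list alone. The infection-induced genes C32H11.4 and sysm-1 changed by 3.11 ± 0.38 and 3.59 ± 0.51. Of 154 cytochrome P450, UDP-glucuronosyltransferase and glutathione S-transferase genes 5 rose and 20 fell, and 10 rose and 32 fell adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). cyp-13A4 changed by -5.66 ± 0.50 and ugt-17 by -3.02 ± 0.27. In heat shock and unfolded protein response 3 of 26 rose and 3 fell, and 6 rose and 3 fell adjusted over the list alone. hsp-4, an endoplasmic reticulum chaperone, changed by 1.09 ± 0.23. The small heat shock gene hsp-12.3 changed by -5.02 ± 0.64, and by -4.34 without WT OP50 replicate 4. Of 18 insulin/DAF-16 targets 2 rose and 4 fell, with the same numbers adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). In iron, metal and sulfide response 3 of 29 fell, among them the hypoxia-responsive rhy-1 (-1.89 ± 0.32) and nhr-57 (-1.4 ± 0.25), and 2 rose and 4 fell adjusted over the list alone.

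Some neural, muscle and histone genes were called in WT as well. Of 74 neuropeptide and insulin-like genes 6 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone (adjusted p = 0.88 with an estimated correlation); flp-33 changed by 2.03 ± 0.32. Of 95 tested chemoreceptor genes, from 1343 in the table, 8 fell, and 1 rose and 8 fell adjusted over the list alone. srh-237 fell from 39.4 ± 20.2 to 0.273 ± 0.187 CPM and str-168 changed by -2.28 ± 0.29. In feeding neuromodulation 1 of 20 fell, daf-16, also adjusted over the list alone (adjusted p = 0.59 with an estimated correlation); its edgeR adjusted p was 0.0507 to 0.109 without each of Methylobacterium replicates 1, 2 and 4. Of 28 muscle genes 5 rose, 11 adjusted over the list alone (adjusted p = 0.59 with an estimated correlation), including the troponins tni-4 (1.2 ± 0.15) and tnt-4 (2.37 ± 0.41). Of 32 histone genes, whose copies share sequence, 5 fell, 10 adjusted over the list alone (adjusted p = 0.59 with an estimated correlation), among them his-40 (-2.02 ± 0.36). Of 27 intestinal genes 2 rose and 2 fell, and 2 rose and 8 fell adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). Of 153 collagens 1 fell, dpy-17 (-1.67 ± 0.31), also adjusted over the list alone. Of 5 embryo markers 1 fell, nhr-176, whose adjusted p was 0.0645 to 0.106 without each of OP50 replicates 3 and 4 and Methylobacterium replicates 1, 2 and 3, and of 12 mitochondrially encoded genes 1 rose, MTCE.35; both were also called adjusted over the list alone. In the other 9 lists edgeR called none of 406 members, with 16 at an unadjusted p under 0.05 and 2 called by DESeq2. They were olfactory signalling, vitellogenins, moulting, sperm, oocyte, germline, male marker, ribosomal protein and respiratory chain genes, and the estimated correlation gave oocyte and germline genes adjusted p of 0.88 and 0.87.

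The largest single changes in WT included F45D11.16, with 2 counts on OP50 and 2178 on Methylobacterium, a ratio of 929 (95% interval 257 to 7679), and its neighbour F45D11.15 (7.27 ± 0.51), whose reads could be shared. pud-3 (7.13 ± 0.54) also rose. F21C10.9 (-8.02 ± 0.58) and clc-24 (-7.57 ± 0.56), a claudin-like gene, fell. The number of calls was 1458 without WT OP50 replicate 2, 498 without WT OP50 replicate 4 and 541 without WT Methylobacterium replicate 2, and the lower calls were 400 without WT Methylobacterium replicate 1. It was 306 when only the 8 WT libraries were fitted, 179 for changes tested against 2-fold, and 1623 with the stage score as a covariate. With the replicate number as a block in the WT libraries, which it was taken to pair, 1373 genes were called (607 higher), 882 of the 907 among them.

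**Figure D2:**
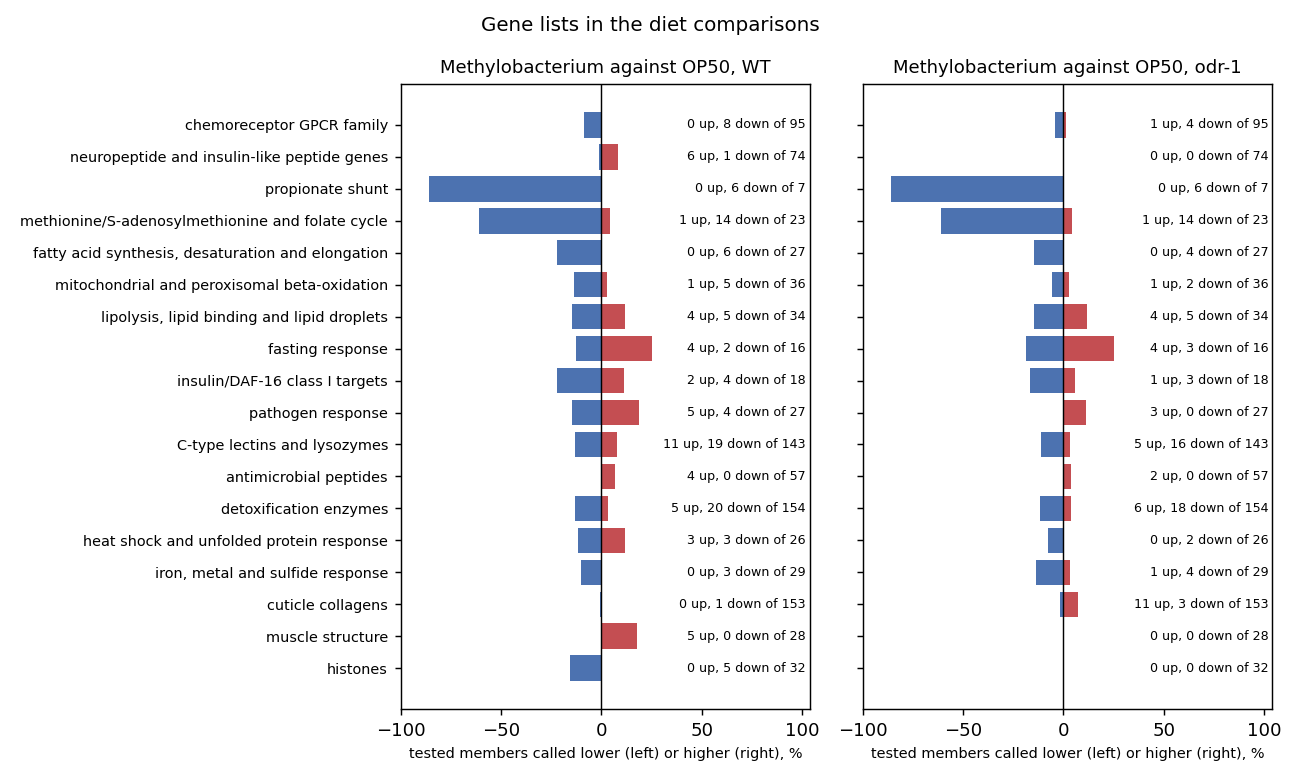
Share of the tested members of each list that was called lower (left, blue) or higher (right, red) on Methylobacterium than on OP50, in percent, in WT and odr-1lf animals (4 libraries per group). Of the propionate shunt genes, 6 of 7 were lower in both genotypes.

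In odr-1lf animals, 6 of 7 propionate shunt genes and 14 of 23 genes of the methionine and folate cycle were lower on Methylobacterium. acdh-1 fell from 3610 ± 352 to 1.1 ± 0.493 CPM, hphd-1 from 1268 ± 176.1 to 51 ± 11 CPM and fat-7 from 180 ± 16.08 to 3.25 ± 2.0 CPM (SD, n = 4). fil-1 rose from 1.41 ± 0.180 to 32.9 ± 11 CPM. The collagen col-50 and the cuticlin cut-1 rose, with most of their signal in a single library.

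edgeR called 444 genes in odr-1lf, 153 higher and 291 lower, and DESeq2 called 1007, of which 549 were higher. The higher share was 34.5% by edgeR and 54.5% by DESeq2. Of the 7 propionate shunt genes 6 fell, 7 adjusted over the list alone. Of the 23 methionine and folate cycle genes 14 fell and 1 rose, with the same numbers adjusted over the list alone. mtrr-1, the methionine synthase reductase, fell from 518 ± 78.6 to 55.6 ± 7.65 CPM and pmp-5 changed by -4.29 ± 0.15. Both lists were called with an estimated correlation (adjusted p = 0.0037 and 0.0027), as the only 2 of the 15 called with the preset value. In the canonical B12-dependent pathway 2 of 8 fell, also adjusted over the list alone (adjusted p = 0.64 with an estimated correlation): mmaa-1 (-1.96 ± 0.20) and cblc-1 (-1.85 ± 0.24). In fatty acid synthesis 4 of 27 fell, 7 adjusted over the list alone (adjusted p = 0.23 with an estimated correlation), with fat-5 at -6.39 ± 0.38 and fat-7 at -5.77 ± 0.38. In beta-oxidation 1 of 36 rose and 2 fell, and 2 rose and 3 fell adjusted over the list alone; cpt-3, with 72 counts on OP50 and 0 on Methylobacterium, was at least 25-fold lower. In lipolysis 4 of 34 rose and 5 fell, and 4 rose and 6 fell adjusted over the list alone, and the fasting regulator mxl-3 changed by -2.91 ± 0.27. In the fasting response 4 of 16 rose and 3 fell, and 5 rose and 3 fell adjusted over the list alone. fil-1 changed by 4.53 ± 0.30 and fil-2 by 4.49 ± 0.45.

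Defence and detoxification genes again moved both ways in odr-1lf. Of 143 lectins and lysozymes 5 rose and 16 fell, and 19 rose and 25 fell adjusted over the list alone, with clec-67 at 2.33 ± 0.29 and clec-170 at -1.47 ± 0.16. Of 154 detoxification genes 6 rose and 18 fell, and 13 rose and 34 fell adjusted over the list alone (adjusted p = 0.67 with an estimated correlation). ugt-17 changed by -2.92 ± 0.27 and cyp-13A4 by -5.84 ± 0.54, and the latter by -6.53 without odr-1lf Methylobacterium replicate 4. In the pathogen response list 3 of 27 rose, 4 adjusted over the list alone (adjusted p = 0.64 with an estimated correlation), including C32H11.4 (3.35 ± 0.38) and irg-3 (2.31 ± 0.30). Of 57 antimicrobial peptide genes 2 rose, 4 adjusted over the list alone (adjusted p = 0.67 with an estimated correlation), and spp-9 reached 106 ± 79.6 CPM from 0.139 ± 0.103 CPM. In iron, metal and sulfide response 1 of 29 rose and 4 fell, and 3 rose and 4 fell adjusted over the list alone, with rhy-1 at -1.68 ± 0.32. In heat shock and unfolded protein response 2 of 26 fell, and 4 rose and 2 fell adjusted over the list alone; hsp-12.3 changed by -3.40 ± 0.59. Of 18 insulin/DAF-16 targets 1 rose and 3 fell, and 5 rose and 3 fell adjusted over the list alone. Of 95 chemoreceptors 1 rose and 4 fell, also adjusted over the list alone, with srh-237 at -5.85 ± 0.57 and str-168 at -2.16 ± 0.29; the list's median of -0.01 turned to 0.0017 with relative log expression factors.

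The stage score and the lists of stage-linked genes were compared between the diets in odr-1lf. The score was -18.5 ± 11 on OP50 and 12.2 ± 12.1 on Methylobacterium (SD, n = 4; exact permutation p = 0.0286, two-sided, the smallest 70 arrangements allow; adjusted p = 0.11 over 4 comparisons). In WT it was 3.32 ± 18.6 and 3.0 ± 19.97 (exact permutation p = 0.97, adjusted p = 0.97). In odr-1lf on OP50, replicates 1 and 3 had scores of -8.67 and -9.30, and replicates 2 and 4 of -28.6 and -27.5. These libraries may not be fully independent, so the permutation p in odr-1lf may be too small. Of 153 collagens 11 rose and 3 fell, and 49 rose and 3 fell adjusted over the list alone (adjusted p = 0.64 with an estimated correlation). The fallen ones included col-64 (-2.68 ± 0.40) and col-132 (-3.46 ± 0.54). Of 88 moulting genes 1 rose, grl-25 (7.86 ± 1.44), also adjusted over the list alone; it was 5.26 without odr-1lf Methylobacterium replicate 1 and 8.49 without odr-1lf OP50 replicate 3. col-50, with 0 counts on OP50 and 1388 on Methylobacterium, was at least 443-fold higher, and its level was 74.2 CPM in odr-1lf Methylobacterium replicate 1 and 0.708 to 3.21 CPM in the other 3 libraries. cut-1, a cuticlin, held 3 counts on OP50 and 826 on Methylobacterium, a ratio of 264 (95% interval 89.98 to 1282); its fitted 8.20 was 5.32 without that replicate 1 and 11.04 without odr-1lf OP50 replicate 3. The 31 oocyte genes had a median log2 fold change of 1.82, with 0 called by edgeR over all genes, 28 adjusted over the list alone, 28 at an unadjusted p under 0.05 and 18 called by DESeq2 (camera adjusted p = 0.64 with an estimated correlation). Vitellogenins, sperm and germline genes had medians of 1.62, 0.62 and 0.38, muscle genes 0.37 and histones -0.45, with estimated-correlation adjusted p of 0.67 in each of these 5 lists. Of 5 male markers 1 fell, also adjusted over the list alone (adjusted p = 0.23 with an estimated correlation), and of 12 mitochondrially encoded genes 1 fell, also adjusted over the list alone. The 13 lists in which edgeR called none of 499 members had 96 at an unadjusted p under 0.05 and 29 called by DESeq2; beside those named they were olfactory signalling, neuropeptide, feeding, embryo, intestinal, ribosomal protein and respiratory chain genes. Adjusted over the list alone, 1 of 27 intestinal genes was higher and 2 were lower.

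**Figure D3:**
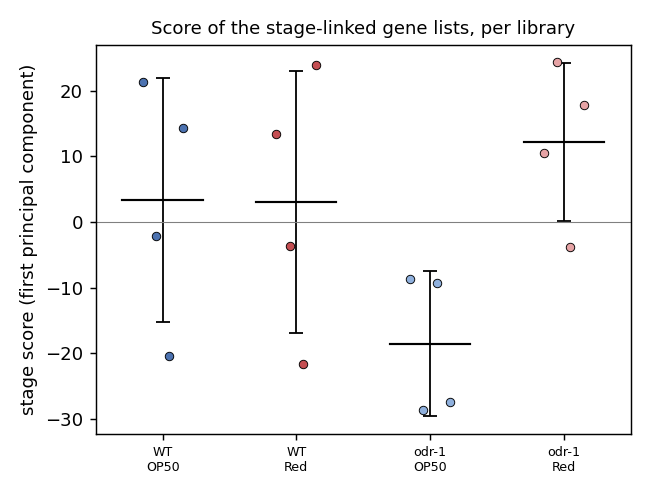
Stage score, the first principal component of 407 stage-linked genes, in each library; points are libraries, long bars are means and whiskers are SD (n = 4). The odr-1lf libraries averaged -18.5 on OP50 and 12.2 on Methylobacterium, while both WT groups spread widely around means of 3.32 and 3.0.

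F21C10.9 (-7.49 ± 0.56) and clc-24 (-6.64 ± 0.54) fell in odr-1lf as well, and C53A3.1, with 432 counts on OP50 and 0 on Methylobacterium, was at least 150-fold lower. The number of calls was 287 without odr-1lf OP50 replicate 2 and 292 without odr-1lf Methylobacterium replicate 4, and the higher calls were 93 without odr-1lf OP50 replicate 4. It was 1095 when only the 8 odr-1lf libraries were fitted and 167 for changes tested against 2-fold.

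The diet calls of both genotypes overlapped. Of the genes called, 316 were called in both in the same direction, 91 higher and 225 lower, where independent lists would share 2.94 and 11.3, and 1 gene was called in opposite directions. This gene was MTCE.35, a protein-coding gene of the mitochondrial genome (11691 to 13272), at 807 ± 270 and 1370 ± 136 CPM in WT and 1206 ± 98.4 and 645 ± 57.1 CPM in odr-1lf on OP50 and Methylobacterium. Its diet call was lost without any of 6 libraries in WT (OP50 replicates 1, 2 and 3 and Methylobacterium replicates 2, 3 and 4; adjusted p 0.0623 to 0.0966) and of 4 in odr-1lf (OP50 replicates 2 and 4 and Methylobacterium replicates 1 and 4; 0.0587 to 0.0732), and its interaction was -1.67 ± 0.27 with an edgeR adjusted p of 0.15, and of 0.0378 with the WT libraries blocked by replicate number. Of the 1034 genes called in either, 947 had the same sign in both, and Pearson's r across those genes, which were chosen by their calls and are not independent replicates, was 0.78. Across all 15640 genes Pearson's r was 0.469 and Spearman's rho 0.342. Shared calls numbered 482 by DESeq2 and 118 for changes tested against 2-fold.

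On OP50, edgeR called few genes between odr-1lf and WT animals. Y39B6A.9 (V, 19136506 to 19139094) rose from 1.08 ± 0.241 CPM in WT to 11.1 ± 1.93 CPM in odr-1lf, and scb-1 from 5.59 ± 1.57 to 24.3 ± 4.04 CPM (SD, n = 4). pgp-6, a P-glycoprotein transporter, fell from 98.6 ± 50.5 to 8.92 ± 2.07 CPM. Its neighbour pgp-7, named after its values were seen, changed by -4.01 ± 0.72, and reads could be shared between them.

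edgeR called 18 genes on OP50, 15 higher and 3 lower in odr-1lf, against 244 by DESeq2, of which 136 were higher; the higher share was 83.3% by edgeR and 55.7% by DESeq2. At an unadjusted p under 0.05 there were 1719 genes, where chance gives 782. cut-3, a cuticlin, changed by 4.19 ± 0.66, the lectin clec-166 by 1.29 ± 0.19 and the chemoreceptor srw-85 by -3.19 ± 0.55. The male marker clec-207 held 1 count in WT and 69 in odr-1lf, a ratio of 67.99 (95% interval 11.8 to 2724). Y39B6A.9 and scb-1 stayed called without any single library. Leaving out libraries ended the call of cut-3 (all 4 WT libraries and odr-1lf replicates 2, 3 and 4; adjusted p 0.0507 to 0.0928), clec-166 (WT replicates 1, 3 and 4 and odr-1lf replicates 2, 3 and 4; 0.0527 to 0.0841), clec-207 (the same 6; 0.0593 to 0.088), srw-85 (WT replicates 2, 3 and 4 and all 4 odr-1lf libraries; 0.0507 to 0.115) and pgp-6 (odr-1lf replicates 2, 3 and 4; 0.0539 to 0.0766). Without WT replicate 1 the fitted log2 fold change of clec-207 moved from 5.56 to 7.21.

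By list, 4 of 143 lectins and lysozymes rose on OP50, 13 adjusted over the list alone (adjusted p = 0.37 with an estimated correlation), 1 of 5 male markers rose, 2 adjusted over the list alone (adjusted p = 0.077 with an estimated correlation), and 1 of 95 chemoreceptors fell, with 1 higher and 1 lower adjusted over the list alone. In the other 29 lists edgeR called none of 1214 members, with 189 at an unadjusted p under 0.05 and 31 called by DESeq2. Adjusted over the list alone, 5 of 74 neuropeptide genes, whose median was 0.50, were higher (adjusted p = 0.67 with an estimated correlation). The same adjustment gave 2 higher and 4 lower of 27 pathogen response genes, 2 higher of 153 collagens, 1 higher each among antimicrobial peptide and intestinal genes, and 1 lower each among propionate shunt genes and histones. Vitellogenins, with a median of -1.57, and oocyte genes, with -1.0, gave adjusted p of 0.67 and 0.94 with an estimated correlation. The preset correlation called 12 of 32 lists and the estimated one 0 (lowest adjusted p = 0.077), with 2 at an unadjusted p under 0.05. The stage score did not differ detectably between these groups (exact permutation p = 0.11, adjusted p = 0.23). The number of called genes was 29, 9, 5 and 4 without WT replicates 2, 3, 4 and 1, and 2 without each of odr-1lf replicates 2, 3 and 4; the lower calls were 1 without odr-1lf replicate 1. It was 1 for changes tested against 2-fold.

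**Figure D4:**
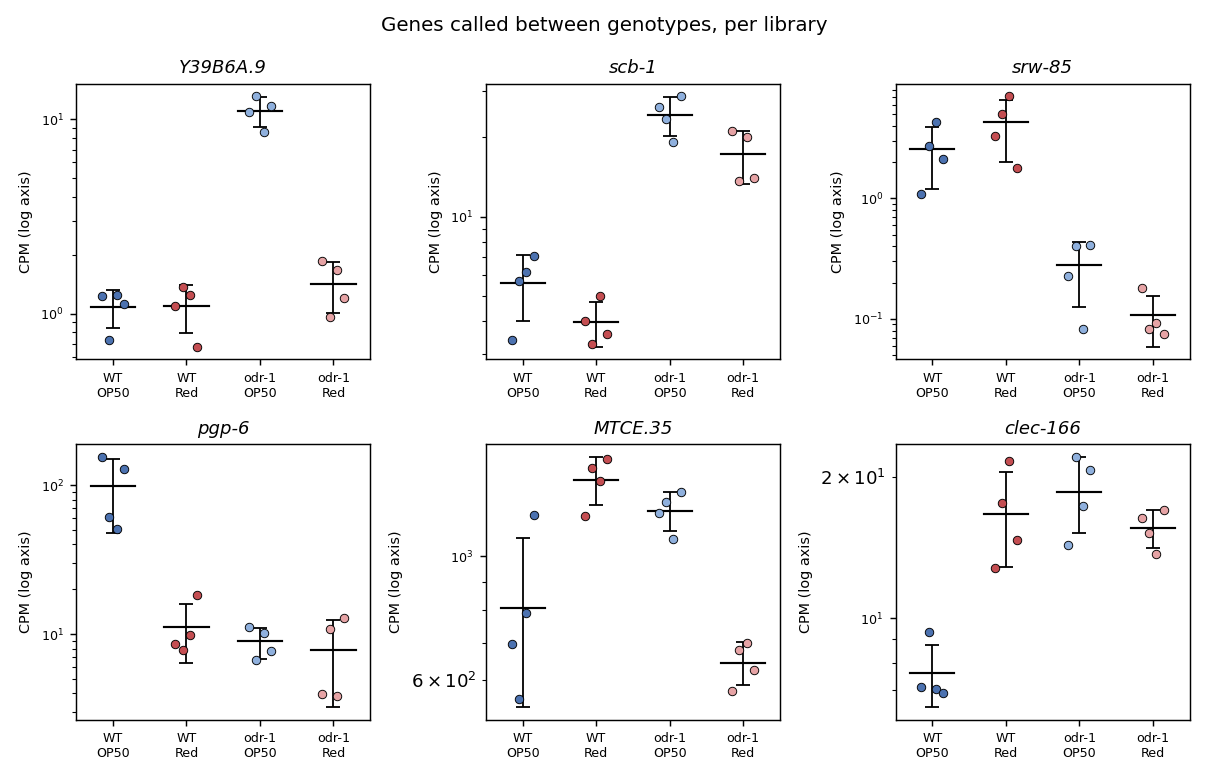
CPM on a log axis in each library of the 4 groups for 6 genes called between genotypes; points are libraries, long bars are means and whiskers are SD (n = 4). scb-1 was higher in odr-1lf on both bacteria, at 24.3 and 17.3 CPM against 5.59 and 3.97 CPM in WT, and Y39B6A.9 stood at 11.1 CPM in odr-1lf on OP50 and at 1.08 to 1.42 CPM in the other groups.

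On Methylobacterium, the largest called fold changes between genotypes lay in neighbouring genes of chromosome V and in cuticle genes. The 9 called genes of a chromosome V stretch were higher in odr-1lf on OP50 too, where edgeR did not call them but DESeq2 called 7. The cuticle signal came mostly from odr-1lf replicate 1. Summed over 9 genes it was 641 CPM there and 6.79 to 42.2 CPM in the other odr-1lf libraries on Methylobacterium. K06H6.2 (V, 585772 to 587336) held 1 count in WT and 3936 in odr-1lf, a ratio of 4356 (95% interval 781 to 172089), and C14C6.6 (V, 545832 to 548080), with 0 and 1106 counts, was at least 408-fold higher. K06H6.1 held 3 and 1614 counts, a ratio of 595 (95% interval 203 to 2890). acdh-1 fell from 3.42 ± 0.563 CPM in WT to 1.1 ± 0.493 CPM in odr-1lf (SD, n = 4). scb-1 rose from 3.97 ± 0.759 to 17.3 ± 3.93 CPM and srw-85 fell from 4.29 ± 2.27 to 0.108 ± 0.0489 CPM.

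edgeR called 28 genes on Methylobacterium, 21 higher and 7 lower in odr-1lf, and DESeq2 called 77, of which 52 were higher; at an unadjusted p under 0.05 there were 650, where chance gives 782. Neighbours such as the K06H6 and C14C6 genes could share reads if they are similar in sequence, which was not examined. The collagen col-36 held 1 and 1529 counts, a ratio of 1692 (95% interval 303 to 66877), and col-2 changed by 9.29 ± 1.54. C13A2.12 held 2 and 743 counts, a ratio of 411 (95% interval 113 to 3401). MTCE.35 changed by -1.09 ± 0.19. The fitted log2 fold changes without odr-1lf replicate 1 were 7.87 for col-36 (10.43 with it), 6.36 for col-2 and 5.85 for C13A2.12 (8.68 with it). They also moved without a WT library, to 11.93 for col-36 (replicate 1), 10.46 for col-2 (replicate 2), 10.92 for C13A2.12 (replicate 3), and 13.04 for K06H6.2 and 9.92 for K06H6.1 (replicate 2), and C14C6.6 moved from 11.21 to 10.31 without odr-1lf replicate 3. Each of the 4 WT libraries, left out, ended the calls of col-36 (adjusted p 0.0673 to 0.119), col-2 (0.0965 to 0.11) and C13A2.12 (0.136 to 0.212). The call of acdh-1 ended without any WT library or odr-1lf replicate 2 or 3 (0.053 to 0.105), that of MTCE.35 without any of the 8 libraries (0.0851 to 0.155), and that of C14C6.6 without WT replicate 1 (0.058).

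By list, 3 of 153 collagens rose on Methylobacterium, 10 adjusted over the list alone (adjusted p = 0.69 with an estimated correlation), and 1 of 7 propionate shunt genes and 1 of 95 chemoreceptors fell, both also adjusted over the list alone. Of 12 mitochondrially encoded genes 1 fell, and 2 rose and 1 fell adjusted over the list alone, where 1 moulting gene and 1 male marker were also higher. In the other 28 lists edgeR called none of 1190 members, with 67 at an unadjusted p under 0.05 and 4 called by DESeq2. Antimicrobial peptide genes, with a median of 0.35, and ribosomal protein genes, with 0.34, each gave an adjusted p of 0.69 with an estimated correlation, and lectins gave 0.37. The preset correlation called 11 of 32 lists, 7 without odr-1lf replicate 1 and 17 without WT replicate 3, and the estimated one called 0, with 1 at an unadjusted p under 0.05. The stage score did not differ detectably (exact permutation p = 0.49, adjusted p = 0.65). The number of called genes was 5, 9, 8 and 11 without WT replicates 1, 2, 3 and 4 and 18 without odr-1lf replicate 3; the lower calls were 4 and 3 without odr-1lf replicates 2 and 4. It was 7 when only the 8 libraries were fitted, 12 for changes tested against 2-fold and 46 with the stage score as a covariate.

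**Figure D5:**
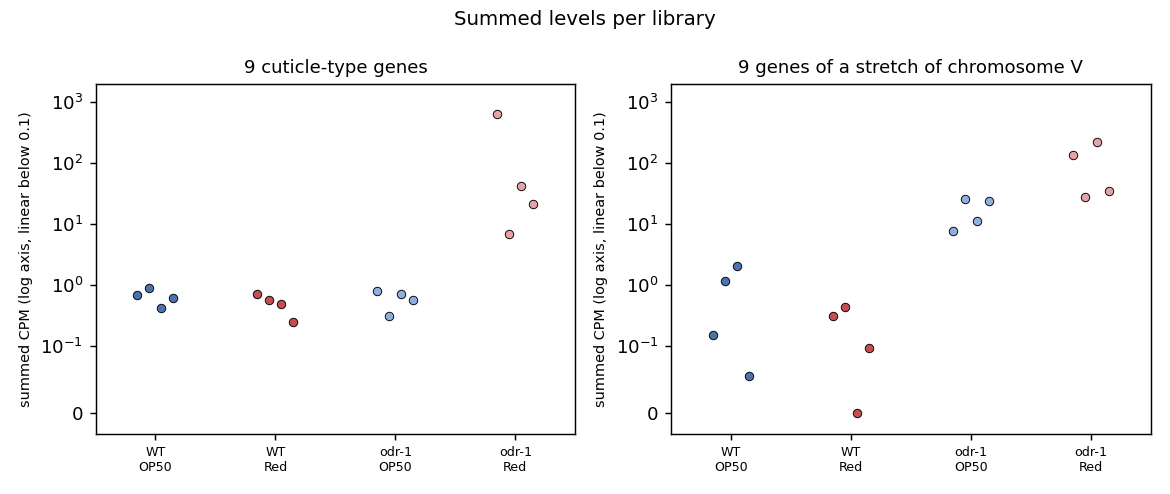
Summed CPM per library, on a log axis that is linear below 0.1, of 9 cuticle-type genes (left) and of 9 genes of a stretch of chromosome V (right), both sets chosen after their values were seen; each point is a library. The cuticle genes reached 641 CPM in odr-1lf Methylobacterium replicate 1 and at most 0.871 CPM in the 12 libraries of the other groups, and the chromosome V genes lay between 7.52 and 218 CPM in odr-1lf and at or below 2.04 CPM in WT.

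Genotype calls shared by both diets were scb-1, higher, and srw-85, lower, where independent lists would share 0.0201 and 0.00134; the number was 12 by DESeq2, 1 with upper-quartile factors or when only the 8 libraries were fitted, 4 with the stage score, and 0 for changes tested against 2-fold. It was 1 without each of WT OP50 replicates 2, 3 and 4, WT Methylobacterium replicate 2 and the 4 odr-1lf OP50 libraries. Of the 44 genes called on either bacterium, 30 had the same sign on both. Across all 15640 genes, which are not independent replicates, Pearson's r between the 2 genotype effects was -0.037 and Spearman's rho -0.145.

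edgeR called 1 gene whose diet effect differed between genotypes. Y39B6A.9 stood at 1.08 ± 0.241 and 1.1 ± 0.303 CPM in WT and at 11.1 ± 1.93 and 1.42 ± 0.418 CPM in odr-1lf on OP50 and Methylobacterium (SD, n = 4), an interaction of -2.99 ± 0.39 (log2, SE; edgeR adjusted p = 0.021). edgeR called no other gene among 15640; 1130 genes were at an unadjusted p under 0.05, where chance gives 782, and DESeq2 called 44, of which 23 were positive (52.3%). The propionate shunt and the methionine and folate cycle had median interactions of 0.33 and 0.09, with 0 called members among their 7 and 23, and adjusted over the list alone 1 shunt gene was negative. The same adjustment gave 1 negative neuropeptide gene, 2 negative lectins, 1 negative mitochondrially encoded gene and 1 positive histone gene. In the 32 lists edgeR called none of 1457 members, with 151 at an unadjusted p under 0.05 and 10 called by DESeq2. The preset correlation called 11 lists and the estimated one 0, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.33. The adjusted p of Y39B6A.9 was 0.0507 to 0.131 without each of 13 libraries, which were all but WT Methylobacterium replicate 4, odr-1lf OP50 replicate 3 and odr-1lf Methylobacterium replicate 1. It was 0.0626 with the replicate number as a block in all libraries, which ended the call, and 0.0378 with the block in the WT libraries only, a fit that called 31 genes, 5 higher and 26 lower. The number of calls was 0 against 2-fold and 6 with the stage score.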

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

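The tests of the cuticle genes, of the diet calls beside the stage score and of the chromosome V stretch were chosen only after the result was seen, while the counts of other splits were planned.

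edgeR called 1 gene whose diet effect differed between genotypes, Y39B6A.9, with an interaction of -2.99. Lists called for the interaction with the preset correlation had medians of -0.30 for neuropeptide genes, -0.53 for feeding neuromodulation, 1.38 for vitellogenins, 0.43 for insulin/DAF-16 targets, 0.37 for pathogen response, 0.45 for collagens, -0.68 for moulting genes, 0.52 for sperm genes, 1.42 for oocyte genes, -1.11 for male markers and 0.58 for histones. None of these 11 list calls held with an estimated correlation (adjusted p = 0.33 or higher).

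In 448 groups of 4 libraries, 34 held a library far from the other 3. In 10 of these that library held 1 to 3 counts of a gene and the others 0, which fixes the outcome. The other 24, among 429 groups where chance gives about 21, included 7 of odr-1lf Methylobacterium replicate 1 and 5 of WT Methylobacterium replicate 3. In odr-1lf Methylobacterium replicate 1 the levels were 74.2 CPM for col-50, 48.7 CPM for col-51, 38.5 CPM for C13A2.12, 42.9 CPM for cut-1, 89.5 CPM for grl-25, 76.7 CPM for col-36 and 103 CPM for col-2. WT Methylobacterium replicate 3 stood apart at 30.7 CPM for F45D11.16, 1.28 CPM for fat-7, 117 CPM for atf-4 and 0.0803 CPM for C13A2.12, and by mean log2 CPM at 6.39 for beta-oxidation and 3.26 for sperm genes. Other WT Methylobacterium libraries did so at 2.94 CPM for his-40, 0.0335 CPM for K06H6.2 and 0.0436 CPM for col-36. In odr-1lf Methylobacterium replicate 2 the 10 most abundant genes took 5.69% of the counts and chemoreceptors had a mean log2 CPM of 0.988, and in replicate 4 hsp-4 reached 760 CPM.

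On OP50 the WT libraries that stood apart held 0.0417 CPM of Y105C5B.7 and of C13A2.12, 16.7 CPM of C53A3.1, 64.3 CPM of clc-24, 0.391 CPM of col-50, 0.0494 CPM of col-51 and of clec-207 and 9.36 CPM of clec-166, with a mean log2 CPM of 5.84 for heat shock genes and 8.51 for muscle genes. The odr-1lf ones held 0.0505 CPM of F45D11.15, 0.0416 CPM of C13A2.12 and of col-36 and 0.125 CPM of cut-1, with a mean log2 CPM of 2.76 for detoxification genes.

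The first pattern is the cuticle genes, whose summed level over 9 genes was 641, 6.79, 42.2 and 20.9 CPM in the odr-1lf Methylobacterium libraries and at most 0.871 CPM in the 12 others. In replicate 3 the genes stood at 3.63 to 9.71% of their levels in replicate 1, and this share differed between genes beyond counting error (permutation chi-square test over genes, p = 1e-04, the smallest that 10000 draws can give, and adjusted p = 3e-04 over 3 libraries), which argues against reads carried over from replicate 1 as the whole cause there. In replicates 2 and 4, with 163 and 560 counts, no such difference was detected (adjusted p = 0.42 and 0.88), so carried-over reads may account for their levels, but a lower level of the same expression would look alike. Developmental stage stays open, as the highest summed level among 6 libraries of other groups in the same range of stage scores was 0.871 CPM, below 6.79 CPM but above the bound set for excluding stage. Larvae with a dauer cuticle stay open too, as 0 of 5 other dauer markers was highest in replicate 1 but some exceeded the median of the other groups there, and a diet response of a few odr-1lf animals was not tested.

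The second pattern is the odr-1lf diet calls beside stage scores that averaged -18.5 on OP50 and 12.2 on Methylobacterium. With the stage score as a covariate, 200 of the 316 calls shared with WT stayed called and their median log2 fold change, counted in the direction of the first call, went from 2.03 to 1.90 (median SE 0.314 to 0.352), which argues against stage as the whole cause of these. Of the 128 calls not shared with WT, 28 stayed called, with this median going from 2.09 to 1.39 (median SE 0.423 to 0.425). For these, stage and diet cannot be told apart, because few calls remained while most of the fold did. An effect of the bacterium in odr-1lf remains open, as untested, for them.

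The third pattern is a window of 60000 bp on chromosome V, where 9 of the 28 genotype calls on Methylobacterium, between 539460 and 592537, lay among 12 tested genes. Random placement gave at most 3 in a window of this length (permutation p = 1e-04, the smallest that 10000 draws can give). The highest WT library reached 2.04 CPM summed over the 9 genes and the lowest odr-1lf library 7.52 CPM. As 5 of 8 odr-1lf libraries lay in the WT range of stage scores, this argues against stage as the whole cause. Within each odr-1lf group, though, the summed level fell as the score rose. On Methylobacterium it was 218 CPM at a score of -3.79 and 27.6 CPM at 24.3. On OP50 it was 25.5 CPM at -28.6 and 7.52 CPM at -8.67. Stage may therefore add to the level in odr-1lf. A strain difference at the locus may be the cause, as 9 of 9 genes had a fold change above 0 on OP50 as well, with a median log2 of 4.23 against 8.31 on Methylobacterium and a lowest interaction adjusted p of 0.47. On OP50 all 9 were at an edgeR unadjusted p under 0.05 and 7 were called by DESeq2. The called gene gmd-2, not among the 12 tested genes of the window and named after its values were seen, had a like profile. It stood at 0.289 and 0.102 CPM in WT and at 4.33 and 25.5 CPM in odr-1lf on OP50 and Methylobacterium. A difference at the locus may therefore not account for all genes of this profile. Strain background and the odr-1 mutation cannot be told apart with a single mutant strain.

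Other splits of the same libraries were fitted for each count. For the diet effect in odr-1lf (444 against 83 at most in other splits) 1 of 35 splits gave as many, the real one included. This share is the smallest possible and was not adjusted over comparisons. It also takes the odr-1lf OP50 libraries as independent, while replicates 1 and 3 and replicates 2 and 4 resembled each other. The share may therefore be too small and does not exclude chance. For the genotype effect on OP50 it was also 1 of 35, but by a margin of 18 against 16. The split with 16 set odr-1lf replicates 2 and 4, which resembled each other, against 1 and 3. The count was 2 without each of odr-1lf replicates 2, 3 and 4, so chance cannot be excluded. For the shared diet calls (316 against 1) and the shared genotype calls (2 against 0) 1 of 60 and 1 of 60 splits gave as many, which decides nothing, because 1 and 0 of the 59 others had calls in both comparisons.

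For the diet effect in WT the splits alone do not exclude chance, as 2 of 35 gave 907 or more, and the highest other gave 2379. That split set OP50 and Methylobacterium replicates 1 and 4, with stage scores of 13.5 to 23.9, against replicates 2 and 3, with -21.6 to -2.09, which points to a structure of the samples that follows stage and the replicate number; with the number as a block in WT, 1373 genes were called. It parted 0 of the same-numbered pairs, and the real split parts all 4. Of the 8 splits that part 4 pairs, which are too few for a share under 0.05, the highest other gave 0. The pairing behind this was read from the same counts. Of the WT calls, 316 were also called in the same direction in the separate odr-1lf libraries, and 532 of the other 591 had the same sign there. Independent lists would share 2.94 and 11.3, but this expectation takes genes as independent. Genes that vary together can overlap more than that, so the overlap alone does not exclude chance.

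For the genotype effect on Methylobacterium, 2 of 35 splits gave 28 or more, the highest 527. For 9 of the 28, the chromosome V genes, levels were higher in odr-1lf in the separate OP50 libraries too. There 9 were at an edgeR unadjusted p under 0.05 and 7 were called by DESeq2, but edgeR called none over all genes. These neighbours may vary together or share reads, so they are not 9 separate observations. The odr-1lf OP50 libraries may not be fully independent either, so these values argue against chance without excluding it. For the interaction 3 of 60 gave 1 or more, the highest 2275. These draws did not keep the pairing taken for WT, and the fit blocked by it, which called more genes, was given no splits. Chance cannot be excluded for either count as a whole, and a structure of the samples is again visible. Chance cannot be excluded for the number of lists called either: 12 of 35 splits gave 13 or more in the diet effect in WT (highest other 22), 10 of 35 gave 15 or more in odr-1lf (20), 15 of 35 gave 12 or more for genotype on OP50 (18), 28 of 35 gave 11 or more on Methylobacterium (24) and 38 of 60 gave 11 or more in the interaction (25).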

How the results depend on the processing

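The fit with the stage score as a covariate, that without ribosomal RNA genes and the block in WT alone were chosen only after the data were seen, and the cause of the changes was not tested. The replicate block in the WT groups, which the numbers were taken to pair, gave 1373 diet calls in WT (607 higher) and 31 interaction calls (5 higher, 26 lower). Among the interaction calls were flp-33, clec-166 and MTCE.35, named for other comparisons (edgeR adjusted p 0.0447, 0.0459 and 0.0378). Calls of the genes named in these comparisons and of the lists it tested did not change. When only the 8 WT libraries were fitted with the block, the calls of ins-28, daf-16, nhr-176 and MTCE.35 ended (adjusted p 0.0517 to 0.139). Outside WT the numbers were not taken to pair libraries. Over all groups, the WT pairs included, 11 of 24 same-numbered pairs had correlated deviations over 0.1 (range -0.42 to 0.711). Some pairs of a WT and an odr-1lf library were among them, up to 0.706 for replicate 3 of WT OP50 and odr-1lf Methylobacterium. Of the 16 libraries, 6 correlated best with their own number. With the replicate block in all groups, genotype calls on OP50 were 7 (5 higher), lower calls on Methylobacterium 4, shared genotype calls 1, and interaction calls 0 lower, as Y39B6A.9 lost its call (adjusted p = 0.0626), and 1 higher, hmit-1.1 (log2 2.7, edgeR adjusted p = 0.0326), named after its values were seen. DESeq2 gave 1384 diet calls in WT (538 higher), 1007 in odr-1lf (549 higher, 458 lower), 244 genotype calls on OP50 (136 higher, 108 lower), 77 on Methylobacterium (52 higher, 25 lower), 44 interaction calls (23 higher, 21 lower), 482 shared diet and 12 shared genotype calls. With only the 8 libraries compared these were 306 in WT (79 higher, 227 lower), 1095 in odr-1lf (636 higher, 459 lower), 1 lower on OP50, 7 on Methylobacterium (4 higher, 3 lower) and 1 shared genotype call. Against 2-fold they were 179 (50 higher, 129 lower), 167 (52 higher, 115 lower), 1 (1 higher, 0 lower), 12 (10 higher, 2 lower) and 0, with 118 and 0 shared. With the stage score they were 1623 in WT (685 higher, 938 lower), 179 lower in odr-1lf, 46 on Methylobacterium (33 higher, 13 lower), 6 in the interaction (4 higher, 2 lower) and 4 shared genotype calls. Without a filter 5 genes were lower on OP50, and upper-quartile factors gave 1 shared genotype call. Leaving out each library in turn gave 498 to 1458 diet calls in WT (165 to 562 higher, 333 to 896 lower), 287 to 407 in odr-1lf (87 to 156 higher, 190 to 251 lower), 2 to 29 on OP50 (2 to 20 higher, 0 to 9 lower), 5 to 35 on Methylobacterium (3 to 31 higher, 2 to 6 lower), 0 to 1 in the interaction (0 higher, 0 to 1 lower), 230 to 342 shared diet and 1 to 3 shared genotype calls. The odr-1 interaction, near 0, changed sign with the block (0.118) and without single libraries (-0.681 to 0.82 over all). Lists changed direction without WT OP50 replicate 3 for oocyte genes in the WT diet effect by their test (median 0.083, from 0.427; -0.043 to 1.028 over all libraries) and by their median without odr-1lf Methylobacterium replicate 1 for the respiratory chain between genotypes (-0.004; highest 0.272). Medians alone changed sign for oocyte genes without WT Methylobacterium replicate 4 in the WT diet effect (-0.043) and without odr-1lf replicate 2 between genotypes on Methylobacterium (-0.016), for lectins on OP50 without odr-1lf replicates 1 (-0.004) and 4 (-0.011), for neuropeptide genes in the interaction without WT Methylobacterium replicate 3 (0.033), and with the stage score for the canonical B12 pathway in the odr-1lf diet effect (0.096) and muscle genes on OP50 (-0.022). With the stage score, directions changed in the odr-1lf diet effect for vitellogenins (-1.253), sperm (-0.147), oocyte (-0.16), germline (-0.231) and histone genes (-0.031, by its test), between genotypes on OP50 for vitellogenins (-0.04, by its test), moulting (-0.173) and oocyte genes (0.654), on Methylobacterium for oocyte genes (-0.042), and in the interaction for neuropeptide (0.286), vitellogenin (-0.865), moulting (0.371), sperm (-0.291) and oocyte genes (-0.724). The score was made from the vitellogenin, sperm, oocyte, germline, moulting and collagen lists themselves. For these lists a change with the covariate was largely built in, so it decides nothing about them. Leaving out libraries ended the call of a named gene in 119 fits and of a list in 81, and an estimated correlation ended 58 list calls and kept 4. At this depth the fold changes of odr-1, with at most 31 counts in a library, were not detectable between genotypes, while T06G6.11, at 0.615 and 0.0602 CPM in WT and odr-1lf on Methylobacterium and named after its values were seen, was called with a larger change (-3.31).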

Other observations

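The families were tested only after the calls were seen, over 140 families of gene names and 560 tests with Benjamini-Hochberg adjustment of a hypergeometric p. This test treats genes as independent, so its p does not measure the spread between libraries and is too small where members vary together. Nuclear hormone receptor genes, which encode ligand-regulated transcription factors, were lower on Methylobacterium more often than independent draws of genes would give: 38 of 191 tested in WT, where 7.40 were expected (adjusted p = 2.79e-14), and 17 in odr-1lf, where 3.55 were expected (adjusted p = 8.5e-06). UDP-glucuronosyltransferase genes were lower in 13 of 59 in WT and 11 of 59 in odr-1lf (adjusted p = 2.14e-05 and 1.36e-06). The detoxification list, which holds these genes, gave camera adjusted p of 0.59 and 0.67 with an estimated correlation.

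Among families that were higher on Methylobacterium in WT, 7 of 11 abu genes were called, where 0.212 were expected (adjusted p = 7.89e-08), along with 8 of 51 pqn genes (adjusted p = 0.000298), 7 of 16 nspc genes (adjusted p = 1.36e-06) and 4 of 18 ins genes, which encode insulin-like peptides (adjusted p = 0.0124). The neuropeptide and insulin-like list gave a camera adjusted p of 0.88 with an estimated correlation in this comparison. In odr-1lf, 5 of 11 nspb genes (adjusted p = 4.14e-06) and 5 of 36 gst genes, which encode glutathione S-transferases (adjusted p = 0.00126), were higher. Of the nspb genes 3 of 11 were higher in WT too (adjusted p = 0.0363). Also higher in odr-1lf were 11 of 134 col genes (adjusted p = 7.48e-06), while the collagen list gave a camera adjusted p of 0.64 with an estimated correlation. Among the called col genes, col-50 and col-51 stood at 74.2 and 48.7 CPM in odr-1lf Methylobacterium replicate 1. In the other libraries of that group they reached at most 3.21 and 1.83 CPM. Members of these families are similar in sequence, so their counts are uncertain where reads were split.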
